A study of Homo sapiens with 6 samples.

How the data were processed

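The series holds RNA-seq of MDA-MB-231 cells, an established human triple-negative breast cancer line, carrying either an empty vector (3 libraries) or shKDM2B, a short hairpin RNA against KDM2B (3 libraries). Per the labels' protocols, total RNA was extracted at subconfluence and libraries were made with a KAPA RNA HyperPrep kit after ribosomal RNA depletion, so transcripts without a poly(A) tail are also captured. The deposited table gives raw read counts per gene, 1 column per library, with versioned Ensembl gene identifiers. The submitters' processing notes name Trim Galore, STAR, featureCounts, DESeq2, edgeR and limma and the build GRCh38 (hg38). Their versions, roles and order, the annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Reads of near-identical genes, of a gene and its pseudogenes and of overlapping or antisense genes can therefore have been split or lost in ways the counts do not show. The hairpin's sequence is not given in the sources used here.

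Columns were assigned to samples by their names, and all 6 were used. The names of the knockdown columns hold sh, an unexplained code and a replicate number, but not KDM2B. They were taken as shKDM2B because it is the only shRNA group of the series. The table has 61533 gene rows, of which 61415 identifiers matched a table of gene names. Biotypes, transcripts and coordinates came from GENCODE release 29 on GRCh38, which holds 58356 of the rows. Library totals ran from 10190149 to 15737951 counts. A count of 0 in a library allows up to 3 counts, or 0.191 to 0.294 CPM (counts scaled to library size) over the 6 libraries, and this floor covers counting error only. The labels call the replicates biological but do not say whether they came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Within each group, every pair of libraries differed beyond sampling noise (chi-square per degree of freedom from 2.10 to 11.1), so no library was counted as a copy of another.

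The design, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Genes were filtered with filterByExpr (minimum count 10, minimum total 15), libraries were scaled by TMM, and shKDM2B was compared with empty vector by edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3, robust empirical Bayes, two-sided) with Benjamini-Hochberg adjustment over the 14071 genes tested. An adjusted p under 0.05 was called a change. Log2 fold changes are shKDM2B relative to empty vector, their standard error (SE) was taken from the fold change and its F statistic, and CPM values are scaled by TMM. The 34 gene lists (9 main, 25 others, 8 of these technical) were tested with limma's camera (limma 3.58.1, preset inter-gene correlation 0.01, log2 CPM with prior count 2), adjusted over the 32 lists with at least 5 measured members. Beside it, camera with an estimated correlation and fry, which tests whether a list's genes move on balance one way without comparing them with other genes, were run.

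The genes named in the results were KDM2B, MYC, ATF4 and the measured members of the PRC1.1 list; the 8 largest increases and 8 largest decreases among changed genes with a mean CPM of at least 5, groups that do not overlap and a symbol that is not a clone, locus, antisense, small RNA or pseudogene name; and up to 4 changed members of each main list and up to 2 of each other list with a mean CPM of at least 5, by size of change. Any other gene is said to be chosen after its values were seen. Alternatives were DESeq2's size factors in the edgeR fit, upper-quartile scaling, scaling without mitochondrial, small RNA and histone genes, no filter beyond 1 read, a filter of 1 CPM in 3 libraries, DESeq2 (1.42.0), limma-voom, no robust step, a replicate block, a test against a 1.2-fold change, a prior count of 0.5 and leaving out each library. A search of annotated 3' UTRs for short sequence words, a length and GC correction and 5 further gene lists were added after the data were seen (Python 3.11.15, scipy 1.17.1). For each gene, the annotated 3' UTR was that of its longest coding transcript only. A word absent there can be present in another transcript of the gene, and the reverse.

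The scripts were tested on counts simulated from these libraries. With 200 genes changed in each of 5 simulations of 13833 to 13866 tested genes, edgeR recovered 28.1% of genes changed 1.25-fold, 66.5% at 1.5-fold, 90.6% at 2-fold and 99.2% at 4-fold, and 9.95% of its calls were false. With a response as broad as the real one, simulated for 13915 tested genes, 88.2% of the changed genes were recovered and 1.93% of calls were false. The genes changed there were those called in the real comparison, each with its estimated fold change. That recovery therefore leaves out changes the real test missed. A serine list shifted 1.5-fold in a simulation of 13849 genes was called with an adjusted p of 4.59e-38 by camera with the preset correlation and 0.0175 with an estimated one. Of 31 other lists, 1 was also called with the preset correlation, and it shares members with the shifted list. All other genes were left unchanged and drawn independently, unlike the real data. These values therefore do not show how the list tests perform in the real comparison. Figures were drawn with matplotlib 3.10.9.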

Results

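Gene expression was measured by sequencing of ribosome-depleted total RNA in MDA-MB-231 cells, a mesenchymal-like triple-negative breast cancer line, with 3 empty vector and 3 shKDM2B libraries. The series asks, per its title, how KDM2B, a histone demethylase and DNA-binding subunit of the noncanonical Polycomb complex PRC1.1, bears on genes of amino acid metabolism together with the transcription factors MYC and ATF4. Library totals were 10190149, 10471185 and 13635565 counts for empty vector replicates 1, 2 and 3. They were 10437732, 11467515 and 15737951 for shKDM2B replicates 1, 2 and 3. The single comparison was shKDM2B against empty vector.

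KDM2B itself fell in every shKDM2B library, with 153, 166 and 224 counts against 589, 714 and 902 in the empty vector libraries. Its level was 63.5 ± 5.58 CPM in empty vector and 14.7 ± 0.183 CPM in shKDM2B cells (SD, n = 3 each), which left 23.1% of the empty vector level. The log2 fold change was -2.12 (SE 0.08, adjusted p 8.77e-11). KDM2B (ENSG00000089094.20) lies on the minus strand of chromosome 12 from 121429097 to 121581015 (GRCh38). ATF4, the main transcription factor of the amino acid stress response, fell 3.41-fold from 460.2 ± 46.4 to 134.8 ± 2.4 CPM (log2 fold change -1.77, SE 0.07, adjusted p 4.55e-11; ENSG00000128272.18, chromosome 22 from 39519695 to 39522685, plus strand). MYC, a driver of ribosome production and growth, fell 1.84-fold from 260.8 ± 12.8 to 141.9 ± 4.71 CPM (log2 fold change -0.88, SE 0.05, adjusted p 5.29e-09; ENSG00000136997.21, chromosome 8 from 127735434 to 127741434, plus strand). All 3 genes had groups that did not overlap. KDM2B holds 2 CGACAC hexamers in the annotated 3' UTR of its longest coding transcript (1019 bases). MYC and ATF4 hold 0 in theirs (476 and 81 bases).

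**Figure D1:**
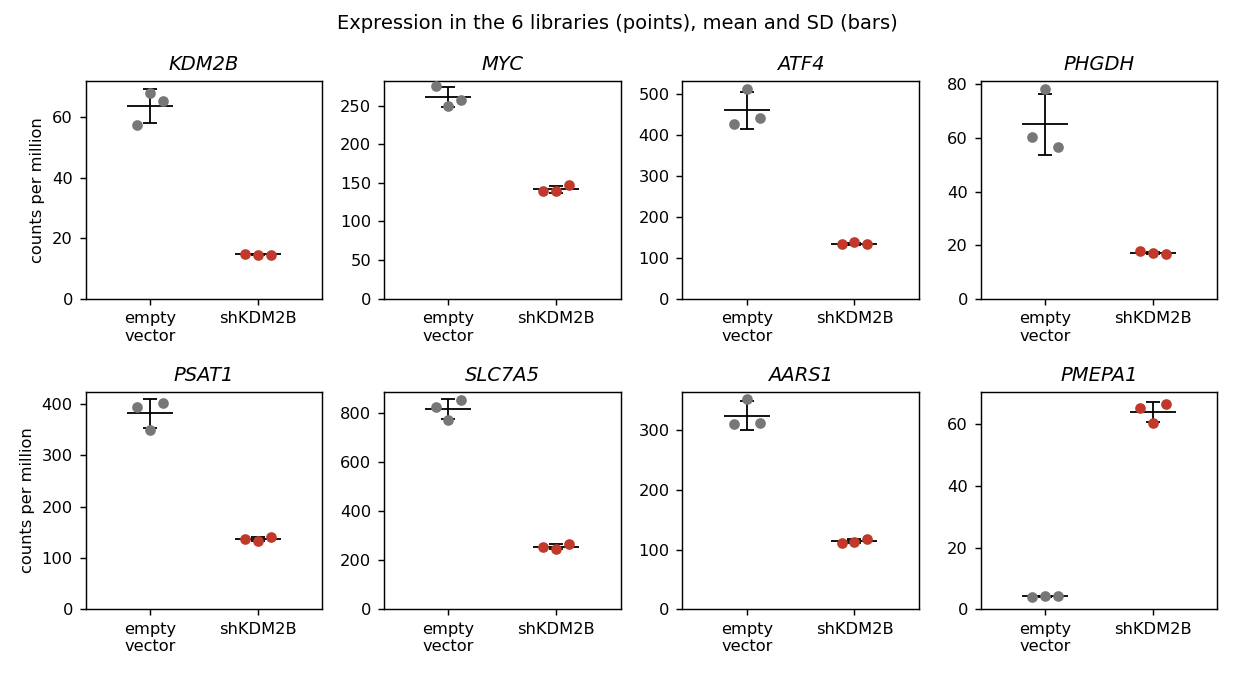
CPM (linear axes from 0) of 8 genes in each of the 6 libraries. Points are libraries, and horizontal and vertical bars are the mean and SD of 3 libraries per group. KDM2B, MYC, ATF4, PHGDH, PSAT1, SLC7A5 and AARS1 lay lower in all 3 shKDM2B libraries, and PMEPA1 lay higher (63.9 against 4.21 CPM).

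The genes of serine synthesis fell together. PHGDH, the first enzyme of the pathway, fell 3.79-fold from 65.1 ± 11.5 to 17.1 ± 0.490 CPM (adjusted p 1.43e-08). PSAT1 and PSPH, which carry out the next steps, had log2 fold changes of -1.48 (SE 0.06) and -1.36 (SE 0.08), and PSAT1 went from 381.9 ± 28.2 to 136.9 ± 4.16 CPM. Of the 21 measured serine, glycine and one-carbon enzymes, 13 were lower, 3 higher and 5 not past the threshold, with a median log2 fold change of -0.44. The list passed the list test (camera adjusted p 0.00416), and its adjusted p was 0.354 with an estimated correlation. SHMT2, the mitochondrial serine hydroxymethyltransferase, chosen after its values were seen, fell with a log2 fold change of -0.99 (SE 0.05). The annotated 3' UTR of SHMT2 holds the hexamer CGACAC, whose presence went with lower counts across genes.

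Other parts of amino acid metabolism held large single decreases without a call for the list as a whole. AHCY, which clears S-adenosylhomocysteine, fell 3.00-fold from 423.4 ± 11.9 to 141.1 ± 3.48 CPM, and CHAC1, which degrades glutathione, fell 7.48-fold from 12.9 ± 1.36 to 1.73 ± 0.138 CPM. AMD1 and ADI1, of polyamine synthesis and methionine salvage, had log2 fold changes of -0.92 and -0.87. In that list of methionine cycle, transsulfuration and glutathione genes, 10 of 20 were lower and 3 higher (camera adjusted p 0.0560), and 4 were higher when adjusted over the list alone. Among 21 measured glutamate, glutamine, proline, aspartate and asparagine enzymes, 12 were lower and 6 higher (camera adjusted p 0.103). Its leading members were GPT2 (log2 fold change -1.11), GLUL, the glutamine synthetase (-1.04), NAGS (-0.97) and PYCR1, of proline synthesis (-0.97). Of 23 branched-chain amino acid catabolism genes, 11 were lower and 3 higher (camera adjusted p 0.0560). HIBADH, a valine catabolism enzyme, fell 6.14-fold from 59.8 ± 3.21 to 9.72 ± 1.45 CPM, and BCAT2 and BCKDK fell by 1.38 and 1.05 on the log2 scale. HIBADH and BCAT2 each hold 1 CGACAC hexamer in the annotated 3' UTR.

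Amino acid transporters went both ways, with 13 of 23 higher, 7 lower and 3 not past the threshold (camera adjusted p 0.161; 14 higher when adjusted over the list alone). SLC7A5, the light chain of the LAT1 carrier of large neutral amino acids, fell 3.21-fold from 818.1 ± 39.7 to 254.9 ± 10.1 CPM. The glycine carrier SLC6A9 fell 2.80-fold, while the creatine carrier SLC6A8 and SLC43A2 rose 3.02-fold and 2.98-fold. The annotated 3' UTRs of SLC6A8 and SLC6A9 each hold 1 CGACAC hexamer.

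Cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, were lower for 19 of 20 genes, and the other did not pass the threshold. AARS1 fell 2.84-fold from 324.2 ± 24.1 to 114.1 ± 3.34 CPM, and CARS1, WARS1 and GARS1 fell 2.31-fold, 1.99-fold and 1.88-fold. The list had a median log2 fold change of -0.46 and a camera adjusted p of 6.81e-07 (adjusted p 0.380 with an estimated correlation). Among 21 measured ATF4 targets of the stress response outside amino acid metabolism, 14 were lower and 4 higher, with a median of -0.84 and a camera adjusted p of 0.0226 (adjusted p 0.381 with an estimated correlation). ADM2 fell 6.64-fold, PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, fell 2.97-fold, and JDP2 fell 2.60-fold. CHAC1, above, also belongs to this list. The 4 members that rose, chosen after their values were seen, were KLHL24, PPP1R15A, CEBPB and VLDLR, with log2 fold changes of 1.29, 0.83, 0.79 and 0.46, and KLHL24 holds a CGACAC hexamer in its annotated 3' UTR. DDIT3, which encodes CHOP, had a log2 fold change of 0.11 with an adjusted p of 0.397 and was also chosen after its values were seen.

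MYC targets of nucleolar and growth function were lower for 39 of 47 measured genes and higher for 0, with a median log2 fold change of -0.43 (camera adjusted p 3.69e-07; adjusted p 0.380 with an estimated correlation). FBL, the fibrillarin methyltransferase of the nucleolus, fell 2.57-fold from 213.0 ± 32.2 to 82.7 ± 2.01 CPM. IMP4, SORD and SLC29A2 had log2 fold changes of -1.32, -1.28 and -1.11. Cytosolic ribosomal protein genes were lower for 44 of 46, with a median of -0.49 (camera adjusted p 1.00e-08; adjusted p 0.381 with an estimated correlation). RPS28 fell 3.79-fold and RPL6 fell 2.43-fold. Ribosomal protein genes have many pseudogene copies, so their counts are uncertain to that extent.

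**Figure D2:**
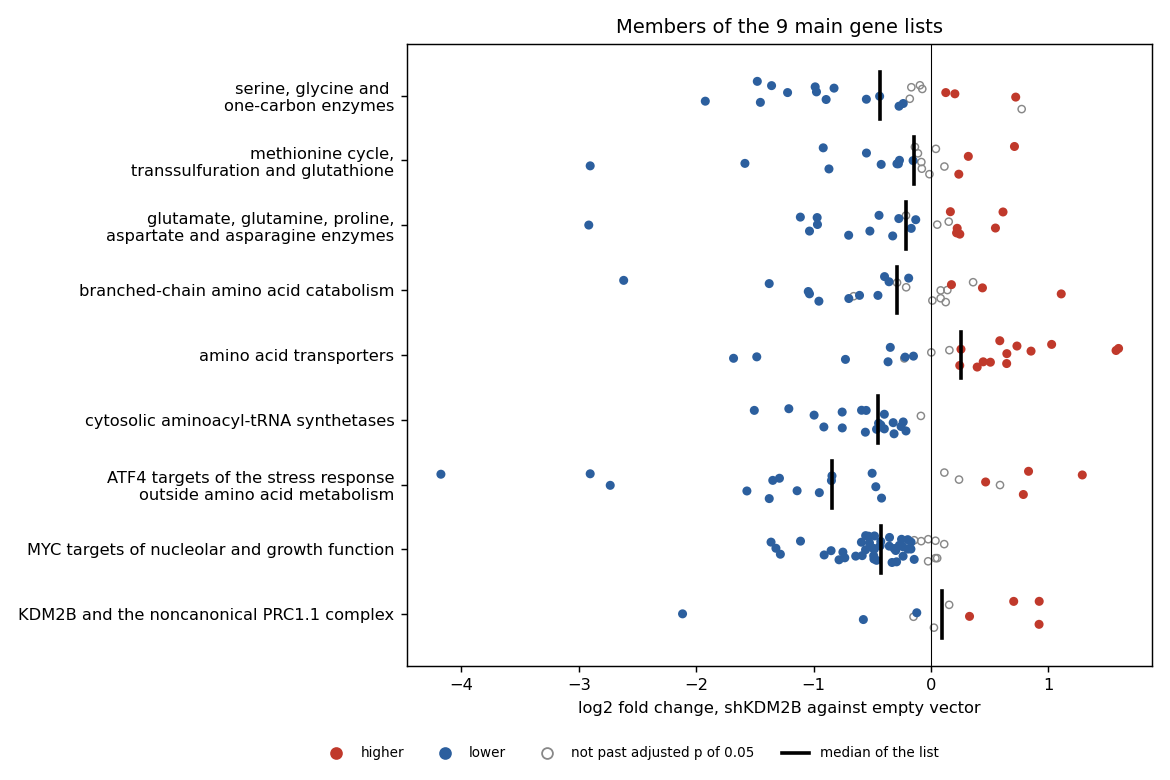
Log2 fold changes (shKDM2B against empty vector) of each measured member of the 9 main lists. Filled points passed an adjusted p of 0.05 (red higher, blue lower), open points did not, and black bars are list medians. Aminoacyl-tRNA synthetases (19 of 20 lower) and MYC targets (39 of 47 lower) lay to the left of 0, while transporters and PRC1.1 members spread to both sides.

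Members of the PRC1.1 complex other than KDM2B did not fall as a group. BCOR rose 1.89-fold from 51.8 ± 2.17 to 97.9 ± 3.6 CPM, its paralog BCORL1 rose 1.89-fold, and the ubiquitin ligases RNF2 and RING1 rose 1.63-fold and 1.25-fold. USP7 fell 1.49-fold. SKP1 fell by 0.12 on the log2 scale (adjusted p 0.0384), a call lost when any 1 of 4 libraries was left out and without the low-count filter. PCGF1 (0.15), RYBP (0.02) and YAF2 (-0.15) did not pass the threshold. For the 10 genes together, KDM2B at -2.12 included, the camera adjusted p was 0.778, with a median of 0.09 and a direction in fry opposite to the median. The list without KDM2B was not tested. Of 26 other PRC1 and PRC2 subunits, 9 were higher and 7 lower (camera adjusted p 0.393), with CBX6 at -1.16 and MTF2 at 0.88 on the log2 scale. Only 7 of 36 HOX genes passed the low-count filter, of which 4 were lower and 1 higher (camera adjusted p 0.255), among them HOXB9 with a log2 fold change of -0.80.

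Of 23 purine and pyrimidine synthesis genes, 20 were lower, among them IMPDH2 (log2 fold change -1.13) and PAICS (-0.69), with a camera adjusted p of 2.40e-04 (adjusted p 0.380 with an estimated correlation). Of 32 DNA replication and G1/S genes, 25 were lower and 1 higher, with GINS2 falling from 39.2 ± 0.849 to 19.5 ± 1.49 CPM and the licensing factor CDT1, which holds a CGACAC hexamer in its annotated 3' UTR, at -0.82 on the log2 scale (camera adjusted p 2.83e-05; adjusted p 0.380 with an estimated correlation). Cholesterol synthesis genes were lower for 14 of 24 and higher for 1 (camera adjusted p 0.00611; adjusted p 0.380 with an estimated correlation). MVD, a decarboxylase of the mevalonate steps, fell 2.22-fold. Interferon-stimulated genes were lower for 15 of 27 and higher for 4 (camera adjusted p 0.0215; adjusted p 0.381 with an estimated correlation), with RSAD2 and OAS2 at -1.58 and -1.57.

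Of 28 measured mesenchymal and matrix genes, 21 were higher and 4 lower, with a median log2 fold change of 0.63 (camera adjusted p 1.63e-04; adjusted p 0.354 with an estimated correlation). The collagen genes COL6A2 and COL1A1 rose 16.8-fold and 11.5-fold. COL6A2 went from 0.727 ± 0.478 to 12.3 ± 0.674 CPM, with 3, 13 and 9 counts in the empty vector libraries, so its fold is uncertain. COL1A1 went from 5.78 ± 1.76 to 66.4 ± 3.70 CPM. The 4 members that fell, chosen after their values were seen, were the matrix proteins TNC (-2.23) and THBS1 (-0.29), the intermediate filament VIM (-1.68), which holds a CGACAC hexamer in its annotated 3' UTR, and the transcription factor SNAI2 (-0.52). Of 16 measured epithelial genes, 9 were higher and 0 lower (camera adjusted p 0.0164; adjusted p 0.380 with an estimated correlation). The tight junction gene CLDN4 rose 2.67-fold and the keratin KRT19 rose 2.05-fold.

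**Figure D3:**
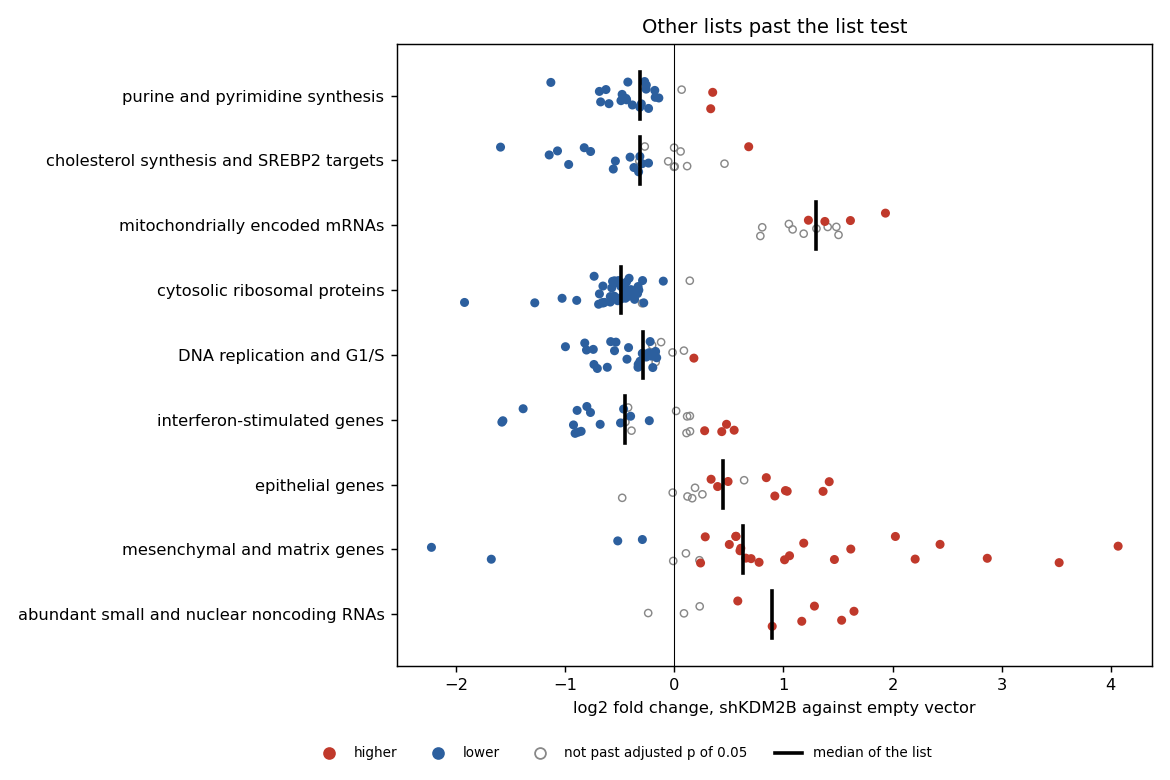
Log2 fold changes (shKDM2B against empty vector) of each measured member of the 9 other lists past the list test, drawn as for the main lists. Ribosomal protein genes (44 of 46 lower) lay to the left of 0. Most matrix genes (21 of 28) lay to the right, with TNC and VIM at -2.23 and -1.68.

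Several further lists did not pass the list test. NRF2 targets had 12 of 20 members higher and 3 lower (camera adjusted p 0.0506, but past the threshold without a filter, at 0.0268, and without empty vector replicate 2 or 3), with the transporter ABCC3 up 3.64-fold and AKR1C3 up 2.06-fold. In glycolysis, 7 were higher and 11 lower of 23 (adjusted p 0.369), and the neuronal-type isoforms SLC2A3 and ENO2 rose 3.52-fold and 2.49-fold. In the hypoxia list, 9 of 19 were higher and 5 lower (adjusted p 0.369), with ANGPTL4 up 10.2-fold and EGLN3 up 2.79-fold. TCA cycle genes were split, 6 higher and 10 lower of 24 (adjusted p 0.650), with DLST at -0.49 and OGDH at 0.39. Of 44 nuclear-encoded respiratory chain genes, 11 were higher and 4 lower (adjusted p 0.369), with NDUFA4 at 0.85 and UQCRB at 0.65. Mitosis genes were higher for 13 and lower for 9 of 34 (adjusted p 0.778), including CDC25C at 0.57 and PTTG1 at -0.55. Of 18 p53 targets, 7 were higher and 5 lower (adjusted p 0.515), with the cell cycle inhibitor CDKN1A up 2.07-fold and TIGAR up 1.96-fold. In the unfolded protein response list, 5 of 21 were higher and 10 lower (adjusted p 0.650), but its leading members DNAJB9 and ERN1 rose 4.21-fold and 1.77-fold, and its mean (0.01) and fry differed in sign from its median (-0.10). NF-kappaB targets had 8 higher and 11 lower of 24 (adjusted p 0.940), with CSF1 up 3.71-fold and IL6 down 3.22-fold, and fry went up where the median was -0.08. Adjusted over the list alone, the counts were the same for 23 of the 34 lists and moved by at most 3 in the other 11.

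Signs of RNA composition differed between the groups. Mitochondrially encoded genes took 0.111 ± 0.0375% of counts in empty vector and 0.326 ± 0.141% in shKDM2B libraries, and MALAT1 took 0.101 ± 0.00576% and 0.287 ± 0.0354%. The 13 mitochondrially encoded mRNAs had a median log2 fold change of 1.30, with 4 past the threshold (1 when adjusted over the list alone) and MT-ND1 and MT-ND4L at 1.93 and 1.61. The call of MT-ND1 (adjusted p 0.0421) was lost with limma-voom, without the filter and when any 1 of 4 libraries was left out. Their camera adjusted p was 0.0226 (adjusted p 0.612 with an estimated correlation), and it was 0.0554 without empty vector replicate 2. Of 9 measured abundant small and nuclear noncoding RNAs, 6 were higher (camera adjusted p 0.0309; adjusted p 0.381 with an estimated correlation), with NEAT1 and MALAT1 up 3.13-fold and 2.89-fold. That call had an adjusted p of 0.0652 without shKDM2B replicate 1, which stood apart with 0.499% of its counts in small RNA genes (0.135 to 0.198% in the other libraries) and 97.3% in protein-coding genes (98.0 to 98.2% in the others). Replication-dependent histones had a median of 0.00249, with 8 higher and 5 lower of 30 (adjusted p 0.940), including H2BC11 at 1.11 and H4C1 at -0.70.

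Few markers of other cell types had enough counts to pass the low-count filter, which is what measured means for all lists here. Of 19 leukocyte markers 3 were measured, 1 higher and 1 lower, with LCP1 at -1.60 on the log2 scale. Of 15 fibroblast markers 3 were measured and all of them were higher, COL1A1 as above, FBLN1 at 0.95 and PDGFRB, chosen after its values were seen, at 2.21. The leukocyte and fibroblast lists were too short for the list test. The fibroblast genes COL1A2, COL3A1, DCN and LUM, chosen after their values were seen, did not pass the filter. They had at most 4 counts each in any library. Of 5 measured endothelial markers, 2 were higher and 1 lower (camera adjusted p 0.650, upward as the mean of 0.36 but against the median of -0.08), with ESAM at 1.58 and KDR, which holds a CGACAC hexamer in its annotated 3' UTR, at 1.56. Of 10 luminal breast markers, 5 were higher and 1 lower (adjusted p 0.0520, but past the threshold without a filter, at 0.0261, and without empty vector replicate 2), including MLPH at 1.06 and KRT19.

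Among changed genes with a mean CPM of at least 5 and groups that did not overlap, the largest increases were in BMF, a pro-apoptotic BH3-only gene, which went from 0.481 ± 0.166 to 39.7 ± 3.20 CPM (log2 fold change 6.39, SE 0.18), and in the orphan receptor GPRC5C (4.84), the calcitonin receptor CALCR (4.57), COL6A2 (4.07), PMEPA1 (3.92), IGFN1 (3.91), the placental phosphatase ALPP (3.88) and the xanthine dehydrogenase XDH (3.82). PMEPA1, a gene induced by TGF-beta, went from 4.21 ± 0.203 to 63.9 ± 3.31 CPM. Under the same limits, the largest decreases were in HLA-DPA1 (-4.22) and HLA-DRA (-3.66), which encode MHC class II chains, in the metalloproteinase PAPPA2 (-3.88), ARHGDIB (-3.57), SYT1 (-3.13), BTBD2 (-2.95), CHAC1 (-2.90) and DMBT1 (-2.89). HLA-DRA went from 57.6 ± 4.68 to 4.49 ± 0.566 CPM and ARHGDIB from 77.0 ± 3.08 to 6.44 ± 0.610 CPM. ARHGDIB, BTBD2 and IGFN1 hold 1, 2 and 1 CGACAC hexamers in their annotated 3' UTRs. Empty vector means of GPRC5C, CALCR, COL6A2, IGFN1, ALPP and XDH lay from 0.459 to 0.960 CPM. The sizes of their increases, like that of BMF, therefore rest on few counts.

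In all, 8571 of 14071 tested genes changed, 4288 higher and 4283 lower, which is 60.9% of those tested. Of these, 1687 changed at least 2-fold, 1004 higher and 683 lower. Groups did not overlap for 9214 tested genes (65.5%, where chance gives 10%). The libraries of a group correlated at 0.990 to 0.994 in log2 CPM and those of different groups at 0.955 to 0.959, and the first principal component, which parted the groups, held 78.2% of the variance. None of the 13 list calls held with an estimated correlation: camera then called 0 lists, with 2 at an unadjusted p under 0.05, while fry called 24. Tested against a 1.2-fold change, 5458 genes were called.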

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

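Removing CGACAC genes and the length and GC trend were chosen after the data were seen. The number of changed genes lay between 7244 (DESeq2) and 8876 (no filter) over the other scalings, filters and tools, and leaving out each library gave 7566 to 9128. DESeq2 shared 7102 calls with the edgeR test and limma-voom 8480, every shared gene in the same direction. Against a 1.2-fold change, 5458 genes were called, 2797 higher and 2661 lower, since that test asks for a larger change. Of the scalings, upper-quartile scaling moved the median of all genes the most, by -0.01 on the log2 scale. KDM2B, MYC and ATF4 kept their direction and call in every setting run, with leave-one-out log2 fold changes from -2.19 to -2.08, from -0.91 to -0.85 and from -1.83 to -1.69. The replicate numbers gave no clear pairing (same-number correlations 0.118, -0.0258 and 0.0751, different-number ones from -0.135 to 0.0838). With 3 libraries per group, a pairing cannot be excluded. A fit with the replicate block called 8479 genes.

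List calls moved more. Lists past the test numbered 13, but 0 with an estimated correlation, 24 with fry, 20 without a filter and 12 to 15 when a library was left out. With an estimated correlation, adjusted p was 0.354 for serine, glycine and one-carbon enzymes, 0.380 for aminoacyl-tRNA synthetases, 0.380 for MYC targets and 0.381 for ATF4 targets. The methionine list (0.0560) had an adjusted p of 0.00479 without a filter, 1.75e-04 with fry, 0.0493 without CGACAC genes and 0.0402 to 0.0840 when a library was left out. The glutamate list had 0.0297 without a filter and 7.22e-04 with fry. Branched-chain catabolism had 0.00798 without a filter, 7.25e-04 with fry and 0.0410 to 0.156 when a library was left out, past the threshold without empty vector replicate 1 or 3. Transporters had 0.00495 with fry. The PRC1.1 list, which includes KDM2B itself, turned down with fry (0.195). Among the other lists, NRF2 targets (0.0506) had 0.0268 without a filter, 0.0443 with the replicate block, 0.0382 and 0.0458 without empty vector replicate 2 or 3 and 0.0452 with the length and GC trend removed. Luminal markers (0.0520) had 0.0261, 0.0443, 0.0328 (replicate 2) and 0.0427 in these settings, and HOX genes (0.255) had 0.0261 without a filter. The fit without a filter tested 35607 genes, and why its list calls were stronger was not tested further.

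Of 1500 values of the other 100 named genes, 1487 kept direction and call. MT-ND1 and SKP1 lost their calls in 11, and RYBP, which was not called, turned to -0.0023 without a filter and lay from -0.0557 (without empty vector replicate 2) to 0.0739 (without empty vector replicate 3) when a library was left out. In simulated data, 28.1% of genes changed 1.25-fold were recovered where 200 genes changed. Where the genes called in the real comparison were given their estimated changes, 88.2% were recovered. The shares cover unlike sizes of change, and the latter leaves out changes the real test missed.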

Other observations

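All of the gene lists, genes and tests below were chosen after the data were seen, except the counts over splits of the libraries. For the splits and the tests of length, GC content and lincRNA genes, the outcome that would count for or against was written before the test was run, and for the tests of seed pairing, base content and fibroblasts after the result was seen. Most genes of MHC class II presentation fell in shKDM2B cells, with 10 of 12 measured members lower, 2 higher and a median log2 fold change of -2.31 (camera adjusted p 3.15e-04 over the 5 added lists; adjusted p 0.0341 with an estimated correlation). CIITA, the master activator of these genes, fell from 29.1 ± 2.07 to 5.54 ± 0.0873 CPM (SD, n = 3), CD74 from 130.1 ± 3.37 to 26.5 ± 0.957, and HLA-DRB1 had a log2 fold change of -4.53. HLA-DRB1 went from 6.45 ± 0.305 to 0.261 ± 0.0656 CPM, which lies within the floor of 0.191 to 0.294 CPM, so its fold is uncertain. HLA genes share sequence, so the split of reads among them is uncertain. In MHC class I presentation, 9 of 16 were higher and 2 lower (camera adjusted p 0.0754; adjusted p 0.363 with an estimated correlation), with HLA-B and B2M at 1.53 and 0.60 on the log2 scale.

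Ligands, receptors and induced genes of TGF-beta signalling were higher for 28 of 30 measured members and lower for 0, with a mean of 1.62 (camera adjusted p 1.86e-12; adjusted p 0.0131 with an estimated correlation). INHBB, LTBP3, SMAD6 and SMAD7 had log2 fold changes of 3.37, 3.04, 2.92 and 1.77, the receptors TGFBR1 and TGFBR2 1.36 and 1.57, and the ligands TGFB1 and TGFB2 1.61 and 1.66. Lysosomal enzymes and membrane proteins were higher for 30 of 37 and lower for 4, with a median of 0.71 (camera adjusted p 6.31e-09; adjusted p 0.0341 with an estimated correlation). SMAD7 and the lysosomal CTSZ each hold 1 CGACAC hexamer in the annotated 3' UTR. CTSD rose from 54.7 ± 2.91 to 289.1 ± 6.82 CPM, and CTSZ and GLA fell by 0.81 and 0.80 on the log2 scale. Cytosolic chaperones of the heat shock response were lower for 14 of 23 and higher for 6 (camera adjusted p 0.0342; adjusted p 0.118 with an estimated correlation), with HSP90AA1 and HSF1 at -1.64 and -1.55. Some members of these lists had been seen to change before the lists were written, so the tests overstate the evidence for them.

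Among 4096 hexamers searched in the annotated 3' UTRs of 10018 genes with a mean CPM of at least 5, CGACAC had the lowest z (-12.3), and 88 of the 377 genes lower at least 2-fold carried it (23.3%, against 5.05% of all searched genes), shares that rest on the same genes that picked it out. A candidate explanation is pairing of the hairpin's seed: CGACAC was the lowest hexamer in the genes of each of 2 sets of chromosomes (odd-numbered and other, even-numbered), and in the set not used to pick it, genes with a 3' UTR site had a mean log2 fold change that differed by -0.242 (SE 0.0557) and -0.295 (SE 0.0551) from that of genes with a site only upstream of the 3' UTR. KDM2B holds CCGACAC in the context GGGATGAGTGAGCCGACACT (chromosome 12 from 121430107 to 121430126, minus strand, GRCh38, exon 23 and annotated 3' UTR of transcript KDM2B-201), and the heptamer CTCATCC, the reverse complement of GGATGAG in it, ranked 8 of 16153 heptamers. Base or CpG content fared worse, since the 29 other hexamers of the same bases with a CpG had a median z of -0.152 (lowest -6.26). A response of these genes to KDM2B loss stays open as untested, since the hairpin's sequence was not given and no other hairpin was analysed here. Dropping the genes that carry a site, without a new fit, left 8132 called genes. That count only removes the 439 changed genes with a site, so it cannot tell whether pairing also altered other genes indirectly. Tested again without the site genes, 14 lists passed.

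MALAT1 and NEAT1 were higher in shKDM2B libraries, and so were 4 of 13 mitochondrially encoded mRNAs (1 when adjusted over the list alone), whose list call was lost with an estimated correlation (adjusted p 0.612) and without empty vector replicate 2 (0.0554). Transcript length and GC content did not account for the mitochondrial part, whose median was 1.30 before and 1.41 after that trend was removed (interquartile range 0.467). A larger share of nuclear RNA, as a cause of the rise of MALAT1 and NEAT1, was expected to raise lincRNA genes too. Their median over 438 genes lay at -0.0716 (bootstrap SE 0.0525) relative to protein-coding genes. That median met the outcome written beforehand as counting against this cause. It cannot decide the question alone, since not every lincRNA need be nuclear. Of 9 abundant small and nuclear noncoding RNAs, MALAT1 and NEAT1 among them, 6 were higher and 0 lower, with a median of 0.90. That list holds the genes to be explained, and its camera call was lost without shKDM2B replicate 1 (adjusted p 0.0652), so it cannot decide either. A larger share of nuclear RNA therefore stays open, with the written outcome against it. Differences in ribosomal depletion or RNA integrity, and a response to the knockdown, stay open as untested.

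Of 28 matrix genes 21 were higher, COL1A1 among them, and COL1A1 is also abundant in fibroblasts. Fibroblasts would bring their other abundant transcripts, but COL1A2, COL3A1, DCN and LUM together reached at most 0.932% of the COL1A1 counts in any shKDM2B library (7 against 751 counts). A response of the cancer cells to the knockdown or to the hairpin stays open as untested.

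The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. For changed genes, genes changed at least 2-fold and lists past the test, 1 split each, the real one, gave a result as large. The real values were 8571, 1687 and 13, and the highest of the other splits were 0, 0 and 10. Those splits had 40 to 169 genes at an unadjusted edgeR p under 0.05. Each of them mixes the groups, so the group difference enters the spread and few genes could be called. They therefore do not show what chance alone gives. They still called 2 to 10 lists each with 0 changed genes, so the list test called lists where no gene was called.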
